A study of Mus musculus with 2 samples.

How the data were processed

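Small RNA libraries with inserts below 30 nt were made from total RNA of pooled embryonic facial prominences, per the labels, which give no extraction or library protocol. The deposited tables hold raw counts of reads per annotated miRNA gene, 1 table per library, on the mouse build mm10 with GENCODE annotation M4, per the text files that accompany the tables. The aligner, its version and its settings are not given in the sources used here. The layout is that of STAR's table of reads per gene, with 4 summary lines ahead of the genes and, for each gene, a count on either strand, a count on the gene's strand and a count on the opposite strand. This reading was tested on the values. In all 1973 genes the first count is the sum of the other 2, and in each of the 3 columns the genes and summary lines add to the same read total. The summary lines name no gene and stayed out of library sizes. In replicate 1, 21.6% of reads were unmapped, 27.6% mapped to several places and 9.01% lay outside the annotated genes on the counted strand, and in replicate 2 these shares were 24.1%, 25.9% and 9.32%. No read was listed as ambiguous. Reads mapping to several places are thus missing from the gene counts, which lowers genes with identical copies elsewhere.

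The count on the gene's strand was used, because its total was by far the larger of the stranded columns (97.6% of gene reads in each library). The unstranded count was an alternative. Gene totals were 2853511 and 3517226 counts. With them, 3 counts, the limit that a count of 0 allows, correspond to 1.05 and 0.853 CPM. CPM was computed from the deposited counts and the totals over all genes. Intervals of shares were exact Clopper-Pearson intervals at 95%.

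Symbols, coordinates, host genes, hairpin sequences and opposite-strand neighbours came from GENCODE M21 (GRCm38, the same build as mm10), a later release than M4, by matching gene identifiers without their version. Of the 1973 identifiers 1894 matched, and the other 79 had at most 3 counts each over both libraries. A host gene is an annotated coding or long non-coding gene on the same strand, with the position given as exon, UTR or intron. An older form of a symbol differing by an added or dropped letter was taken as the same list member. A hairpin was called similar to another where both hold an identical stretch of 20 bases in either orientation.

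The samples were grouped by the labels into 1 group of 2 biological replicates, so no contrast between conditions was fitted. The tests, the gene lists and 36 alternatives were set before the data were examined, and 6 alternatives were added afterwards. A gene was called detected with at least 10 counts in each library. The ratio between the libraries is log2 of CPM in replicate 2 over replicate 1 with a pseudocount of 0.5 CPM, summarised over genes with a mean of at least 10 CPM, with 1000 bootstrap resamples of the genes. Each gene with at least 10 counts in all was tested by a two-sided exact binomial test against the share expected from the library totals, with Benjamini-Hochberg adjustment over the 449 genes and a threshold of 0.05. The biological coefficient of variation was the square root of the common dispersion that edgeR estimated with an intercept only and TMM factors (0.997 and 1.00), with 100 resamples of the genes. For each of 16 gene lists the CPM were summed, and the median ratio of the detected members was placed among 10000 random lists of the same size. Random members were drawn from the 15 nearest genes in mean CPM on each side. Genomic clusters joined miRNA genes within 10 kb on the same strand. The SD over 2 libraries is their absolute difference divided by the square root of 2.

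The genes named were chosen by a rule set before the data were examined. It takes the 20 genes with the highest mean CPM, the 3 highest detected members of each list, the 5 genes most raised and the 5 most lowered in replicate 2 among tested genes with a mean of at least 10 CPM that passed, and the 3 highest members of the 5 highest genomic clusters, 65 genes in all. A gene named as the lowest of a cluster, genes at which opposite-strand reads were counted and their partners, and the genes of the added imprinted and neural checks lie outside this rule and were chosen after their values were seen.

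The procedures were tested on simulated data. In counts simulated for 741 genes in replicate 2 against replicate 1, with counting noise only, and among those with at least 10 counts in all, the exact binomial test called 44 of 56 genes changed 2-fold (78.6%), 42 of 67 changed 1.5-fold (62.7%) and 2 of 333 unchanged genes (0.6%). Of 200 unchanged lists of 8 genes drawn from 376 genes, 11 (5.5%) fell outside the central 95%, and of 200 lists raised 1.5-fold 198 (99%) were found. The simulated ratios were independent between genes, and list members were drawn at random. The 5.5% therefore need not hold for lists whose members share a genomic cluster. For simulated coefficients of variation of 0.1, 0.2 and 0.3 between the replicates over 376 genes, the mean estimates were 0.099, 0.199 and 0.297.

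Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, the last for size factors only. The alternatives were leaving out each replicate, the unstranded count, other count and CPM minimums, a pseudocount of 5 CPM, equal depth, leaving out the highest gene, TMM and DESeq2 scaling, a cluster gap of 50 kb and another definition of multi-copy genes. The alternatives added later left out members with a shared 20-base stretch or members under a mean of 10 CPM, or took 1 value per genomic cluster, the median over the list's detected members in it, against random lists of as many clusters or lone genes, or compared multi-copy genes with all genes under either definition. The limit of the multi-copy comparison to genes with a Mir symbol was not set before the data were examined. Signal tracks and alignments were not used here.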

Results

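MicroRNA sequencing was used to profile the facial prominences of mouse embryos of the B6NCrl strain at embryonic day 10.5. The prominences are the outgrowths of neural crest mesenchyme and covering epithelium that form the face and jaws. The series holds 1 group of 2 biological replicates, a pool of 69 embryos (replicate 1) and a pool of 51 embryos (replicate 2), each of both sexes. There is no second stage, tissue or treatment among these samples, so the comparisons are between miRNA genes and gene groups within the tissue, and between the 2 pools. The libraries held 6828248 reads (replicate 1) and 8643947 reads (replicate 2), of which 2853511 (41.8%) and 3517226 (40.7%) were counted on the strand of an annotated miRNA gene. Levels are given as CPM, the gene's count scaled to the library's total of such counts, or as a percentage of that total, as mean ± SD over the 2 libraries (n = 2). Ratios are replicate 2 over replicate 1. Intervals and tests on counts cover counting error only, since reads amplified by PCR are not independent molecules. The count of a gene sums both arms of its hairpin, and small RNA libraries favour some sequences, so differences between genes are differences in reads.

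The profile was led by Mir335 and Mir17. Mir335 was the highest gene, with 15.4% ± 0.472 of all counts (ENSMUSG00000065501.1, chromosome 6, 30741299 to 30741396, mm10). It lies in an intron of Mest, an imprinted gene of embryonic mesoderm. Mir17 followed with 10.2% ± 0.243 (ENSMUSG00000065508.1, chromosome 14, 115043671 to 115043754, in an exon of its host transcript Mir17hg). Both libraries had Mir335 above Mir17, and the gap between them was larger than the difference between the libraries for either gene. By mean level the next genes were Mir99a with 4.09% ± 0.317, Mir20a with 3.98% ± 0.165, and Mir126a, an endothelial miRNA in Egfl7, with 3.30% ± 0.193. Mir130a took 3.19% ± 0.124, Mir26b 2.70% ± 0.0416, Mir322 2.54% ± 0.0307, Mir99b 2.52% ± 0.101 and Mir30e 2.22% ± 0.346. These 10 genes held 50.1% ± 0.125 of all counts, with an exact Clopper-Pearson 95% interval of 50.1% to 50.2% in replicate 1 and 49.9% to 50.1% in replicate 2. The other genes among the 20 highest were Mir93, Mir182, Mir18, Mir106b, Mir214, Mir130b, Mir183, Mir100, Mir487b and Mir92-1, from 2.06% down to 0.970%. Mir100, in the same family as Mir99a and Mir99b, had 1.13% ± 0.0599, and Mir130b, a relative of Mir130a, had 1.30% ± 0.0554. Of 1973 genes in the tables, 376 had at least 10 counts in each library and 1232 (62.4%) had no count in either. A count of 0 allows up to 1.05 CPM in replicate 1 and 0.853 CPM in replicate 2 (3 counts). The 69 highest genes made up 90% of the counts.

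Among 16 gene lists fixed before the data were examined, the Mir17-92 cluster and its paralogs, which promote cell proliferation, had the highest sum, 221544 ± 3916 CPM (22.2% of counts). All 15 members were detected, with Mir17 at 101576 ± 2425 CPM, Mir20a at 39804 ± 1645 CPM and Mir93 at 20569 ± 222 CPM. The miRNA genes of the imprinted Dlk1-Dio3 region came next, with 76312 ± 1946 CPM (7.63%) and 40 of 43 matched members detected. Its highest matched members were Mir487b with 9738 ± 183 CPM, Mir411 with 9126 ± 721 CPM and Mir431 with 8727 ± 890 CPM. Mir409 had no matched gene and is outside the sum. Reads on its strand at Gm24321, which overlaps it, came to 9122 CPM in replicate 1 and 9881 CPM in replicate 2. The Sfmbt2 intron cluster, best known from placenta, had 5053 ± 621 CPM over 107 genes within 10 kb of a neighbour. The 21 matched members of its list summed to 4226 ± 615 CPM. Its highest members were Mir467c with 1605 ± 254 CPM, Mir467d with 1511 ± 244 CPM and Mir467e with 994 ± 120 CPM. These Sfmbt2 values are uncertain, because 20 of the 21 matched members share a 20-base stretch with another miRNA gene, and the list summed to 0.89 CPM without them.

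Markers of both main tissue layers of the face were abundant. The mesenchyme and neural crest list summed to 48442 ± 3975 CPM (4.84% of counts), with 12 of 13 members detected. Mir214, made from the Dnm3os transcript that is expressed in mesenchyme, led it with 14538 ± 1041 CPM, ahead of Mir23b with 8668 ± 483 CPM and Mir143 with 8449 ± 846 CPM. The epithelial list (the Mir200 family, Mir205 and Mir203) summed to 26328 ± 3342 CPM (2.63%), with all 7 members detected. It was led by Mir205, a miRNA of surface epithelium, with 9187 ± 710 CPM, followed by Mir429 with 7419 ± 995 CPM and Mir200c with 3416 ± 35.1 CPM. The sum of the mesenchymal list was above that of the epithelial list in both libraries. The Mir183 cluster, known from sensory organs and placodes, summed to 31677 ± 6201 CPM (3.17%), with Mir182 at 15336 ± 4663 CPM, Mir183 at 11430 ± 971 CPM and Mir96 at 4911 ± 567 CPM. The endothelial list rested on Mir126a alone, with 33005 ± 1928 CPM.

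Markers of early embryonic cells were present beside the let-7 family, which accumulates as cells differentiate. The Mir290 and Mir302 clusters, known from pluripotent cells, summed to 17115 ± 4900 CPM (1.71%), and 11 of 12 matched members were detected. Nearly all of this came from the Mir302 cluster, with 16701 ± 4784 CPM, and the Mir290 cluster had 414 ± 116 CPM. Mir302a had 6635 ± 1809 CPM, Mir302d 5071 ± 1347 CPM and Mir302b 4097 ± 1352 CPM, all within a cluster on chromosome 3 (127545228 to 127545807). The let-7 family summed to 7589 ± 3080 CPM (0.759%), with 9 of 10 matched members detected. Among matched members, Mirlet7g, in an intron of Wdr82, had 4410 ± 1540 CPM, Mirlet7i 2432 ± 1328 CPM and Mirlet7d 330 ± 72.5 CPM. Mirlet7e had no matched gene and is outside the sum. Reads on its strand at Gm25927, which overlaps it, came to 2396 CPM in replicate 1 and 1814.5 CPM in replicate 2. Without members that share a 20-base stretch with another miRNA gene, the Mir290 and Mir302 clusters summed to 6349 CPM and the let-7 family to 7444 CPM, so no order is given for the 2 lists.

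Over all members, the 7 lowest sums were those of other cell types and body regions. The neural list summed to 3077 ± 1367 CPM, and to 1036 CPM without members that share a 20-base stretch. Its highest members by mean were Mir219a-2 with 1278 ± 1328 CPM, Mir137 with 636 ± 62.0 CPM and Mir219a-1 with 402 ± 145 CPM. Mir219a-2 led the list in replicate 2 only, and Mir137 did so in replicate 1. The eye, lens and endocrine list summed to 2440 ± 18.4 CPM, with Mir375 at 1389 ± 141 CPM, Mir204 at 402 ± 0.290 CPM and Mir211 at 321 ± 92.2 CPM. The Hox and posterior axis list summed to 506 ± 181 CPM, with Mir10a at 251 ± 135 CPM, Mir10b at 164 ± 20.7 CPM and Mir196b at 65.7 ± 20.5 CPM. The leukocyte list had 458 ± 5.09 CPM, with Mir223 at 249 ± 5.91 CPM, Mir155 at 175 ± 12.6 CPM and Mir146 at 29.1 ± 1.94 CPM. Its sum was 1128 CPM in the unstranded count, which adds reads on the strand opposite Mir142b. The erythroid list had 312 ± 152 CPM (420 in replicate 1 and 205 in replicate 2), with Mir451a at 251 ± 152 CPM, Mir144 at 39.2 ± 3.11 CPM and Mir486 at 22.5 ± 3.57 CPM. The liver list had 155 ± 5.05 CPM, and 88.4 CPM without members that share a 20-base stretch, with Mir192 at 73.1 ± 1.67 CPM, Mir194-2 at 65.8 ± 6.14 CPM and Mir122 at 13.98 ± 1.94 CPM. The striated and cardiac muscle list had the lowest sum, 110 ± 38.1 CPM, with Mir208b at 69.3 ± 44.0 CPM, Mir206 at 18.4 ± 11.2 CPM and Mir208a at 9.86 ± 2.54 CPM. Of the 120 pairs of lists, 110 were separated in both libraries by more than the larger ratio between the libraries of the lists compared. That count uses the sums over all members. It includes the let-7 list against the Mir290 and Mir302 list, for which no order is given. It also includes pairs with the Sfmbt2 list, which summed to 0.89 CPM without members that share a 20-base stretch. With 2 libraries no exact test between lists can reach 0.05. Sums of lists with multi-copy members are low in part by construction, because reads that map to several places were not assigned to a gene, and 13 of 15 neural, 5 of 9 muscle and 5 of 10 let-7 members share a 20-base stretch with another miRNA gene.

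**Figure D1:**
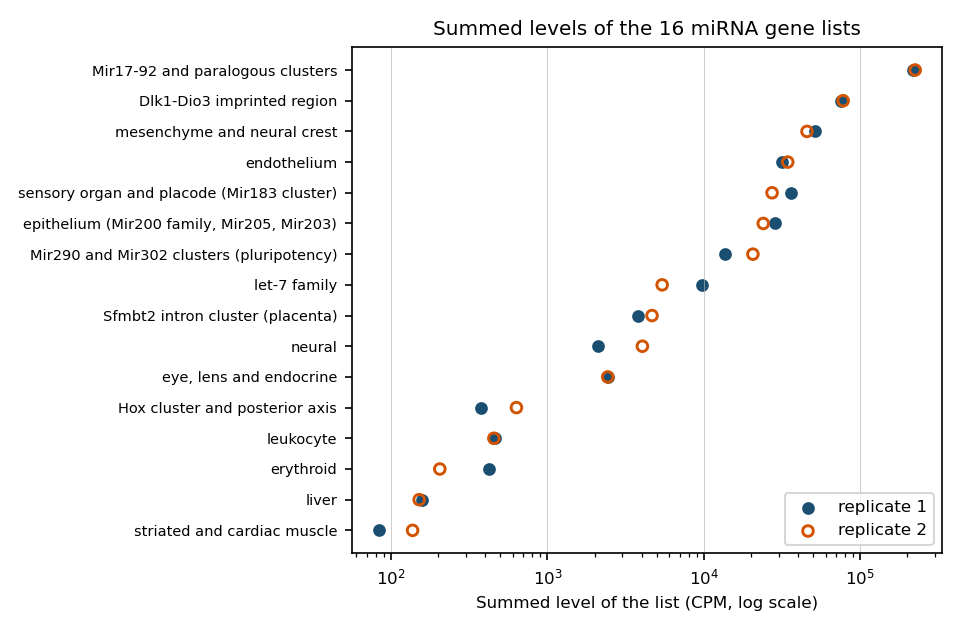
Summed level of each of the 16 gene lists on a log scale in CPM, with a filled circle for replicate 1 and an open circle for replicate 2. The sums run from 110 CPM (striated and cardiac muscle) to 221544 CPM (Mir17-92 and paralogs) as means of the 2 libraries.

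Most counts came from miRNA genes that lie close together. Genes within 10 kb of a neighbour on the same strand formed 104 genomic clusters with 414 genes and 60.4% of the counts, and the 5 highest clusters held 32.8%. The Mir17-92 cluster on chromosome 14 (115043671 to 115044506) held 16.6% ± 0.0635, but its members were unequal. Among the members that share no 20-base stretch with another miRNA gene, Mir17 had 453 times the CPM of Mir19a, the lowest (224 CPM), and Mir18 had 15075 ± 739 CPM. The distal part of the Dlk1-Dio3 region on chromosome 12 (109709060 to 109747960) held 5.20% ± 0.0672 in 34 genes, 30 of them detected, with Mir369 (7415 ± 154 CPM) behind Mir487b and Mir411. The cluster of Mir99a and Mirlet7c-1 on chromosome 16 (77598936 to 77599750) held 4.09% ± 0.317, with Mir99a at 40876 ± 3170 CPM and Mirlet7c-1 at 19.97 ± 0.50 CPM. Mirlet7c-1 shares sequence with other let-7 copies, so its level is uncertain. The cluster in Mcm7 on chromosome 5 (138165321 to 138165818) held 3.68% ± 0.0732, with Mir93, Mir106b (14900 ± 1001 CPM) and Mir25 (1287 ± 47.3 CPM). The Mir183 cluster on chromosome 6 (30165918 to 30169737) held 3.17% ± 0.620.

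**Figure D2:**
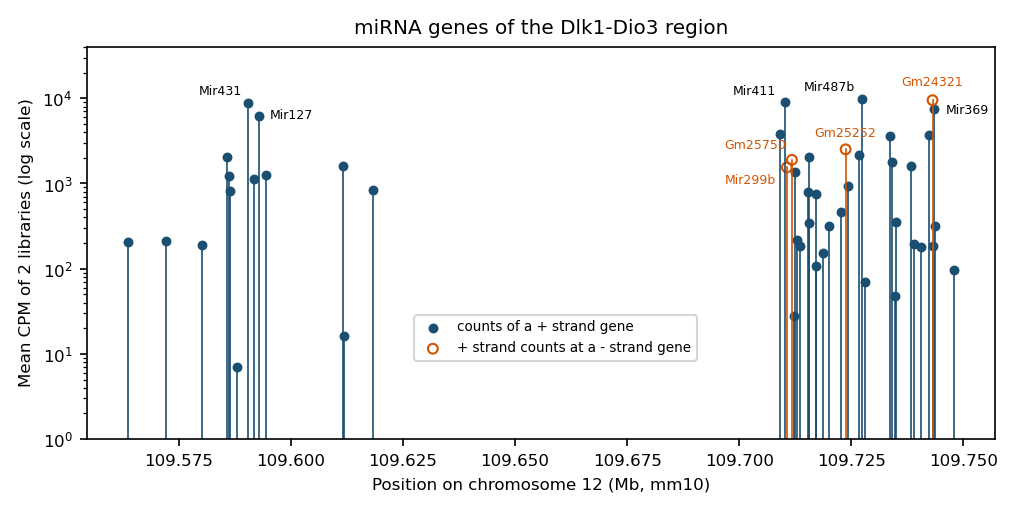
Mean CPM of the 2 libraries (log scale) at each detected miRNA gene of the Dlk1-Dio3 region by position on chromosome 12 in Mb (mm10), with filled circles for the 44 genes on the plus strand and open circles for plus-strand counts at 4 genes annotated on the minus strand. The 4 open circles lie between 1545 and 9502 CPM, and the filled circles reach 9738 CPM at Mir487b.

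The 2 pools gave close profiles, with a few genes well apart. Over 320 genes with a mean of at least 10 CPM, 287 (89.7%) lay within 1.5-fold and 311 (97.2%) within 2-fold between the libraries, and 9 differed by more, 3 higher and 6 lower in replicate 2. The SD of the log2 ratio was 0.39 (95% bootstrap interval over genes 0.33 to 0.46) and its median 0.03. Across genes, Pearson's r of log2 CPM was 0.992 and Spearman's rho 0.991; genes are not independent replicates. The biological coefficient of variation estimated with edgeR was 0.176 (95% bootstrap interval over genes 0.145 to 0.20). That interval does not cover the uncertainty from having only 2 libraries. By exact two-sided binomial tests with Benjamini-Hochberg adjustment, 181 of 449 genes differed between the libraries, 90 higher and 91 lower in replicate 2. Of these, 17 differed at least 2-fold, 6 higher and 11 lower. These tests compare the 2 libraries beyond counting error and not conditions. The labels give the libraries as 2 biological replicates, and their counts differed by more than sampling noise (chi-square per degree of freedom 83.9), so they are not 1 library counted again.

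**Figure D3:**
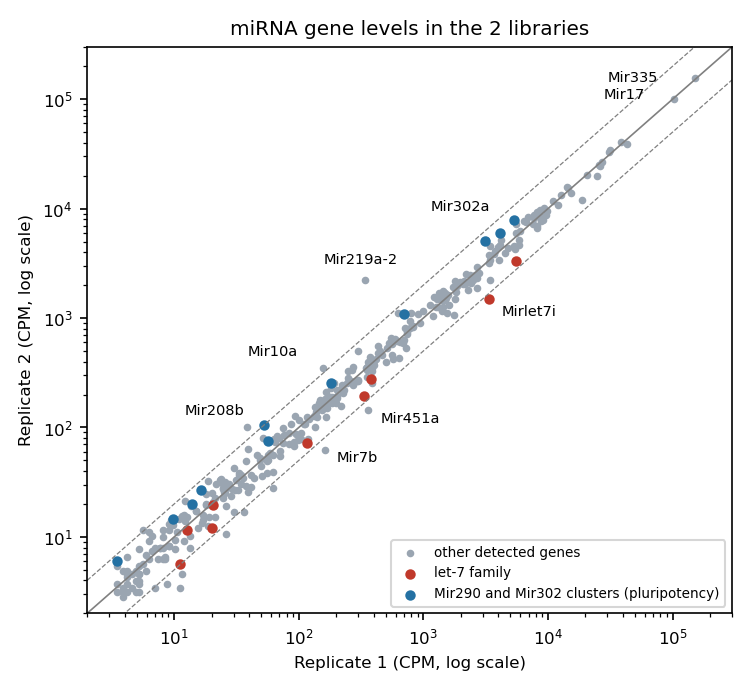
CPM of each of the 376 detected miRNA genes in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales, with the line of equality and dashed lines at 2-fold, and with let-7 genes in red and Mir290 and Mir302 cluster genes in blue. Mir219a-2 lies farthest above the line, at a log2 ratio of 2.71.

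The let-7 family and the Mir290 and Mir302 clusters differed between the pools in opposite directions. All 9 detected let-7 genes were lower in replicate 2, 7 of them past the exact binomial test (7 adjusted over the list alone), with a median log2 ratio of -0.72. Mirlet7i had a log2 ratio of -1.18, Mirlet7g -0.73 and Mirlet7d -0.45, and the summed level was 1.81-fold higher in replicate 1. All 11 detected genes of the Mir290 and Mir302 clusters were higher in replicate 2, 8 of them past the test (8 adjusted over the list alone), with a median of 0.56. The ratios of Mir302a, Mir302d and Mir302b were 0.56, 0.55 and 0.69. Among 10000 random lists of detected genes matched on level, none had a median as low as the let-7 list and none as high as the Mir290 and Mir302 list. Counted as 1 value per genomic cluster or lone gene, the let-7 list stayed outside the central 95% (7 values, percentile 0.01), while the Mir290 and Mir302 list, with 2 values, lay inside it (percentile 97.1).

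Smaller shared differences were seen in lists of the tissue layers. The epithelial list was lower in replicate 2 in 7 of 7 genes, 6 past the test (6 adjusted over the list alone), with a median log2 ratio of -0.27 (percentile 0.20 of the random lists). Mir205 and Mir429 had ratios of -0.16 and -0.27, while Mir200c, at -0.02, did not pass. The mesenchyme and neural crest list had a median of -0.20 (percentile 0.36, and 4.12 with 1 value per cluster), with 8 genes lower and 1 higher past the test (9 adjusted over the list alone), among them Mir214 at -0.15, Mir23b at -0.11 and Mir143 at -0.21. The Mir183 cluster had a median of -0.24 (percentile 1.33), with 3 of 3 genes past the test (3 adjusted over the list alone) and Mir182 at -0.63. The Hox list was higher in replicate 2, with a median of 0.46 (percentile 99.6) and 3 of 5 genes past the test (3 adjusted over the list alone), Mir10a, Mir196b and Mir10b. The Mir17-92 list had a median of 0.14 (percentile 99.0), with 9 genes higher and 3 lower past the test (12 adjusted over the list alone). That median fell to 0.10 (percentile 91.7) without members that share sequence with another gene, and to 0.09 (percentile 83.0) with 1 value per cluster. The Sfmbt2 list had a median of 0.29 (percentile 98.5), with 3 of 6 genes past the test, Mir467c, Mir467d and Mir467e (4 adjusted over the list alone). Its percentile was 94.7 with every member that had a count.

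The neural list gave different signs by median and by sum. Its median log2 ratio was -0.28 (percentile 1.22), with 5 genes lower, Mir137 among them at -0.20, and 2 higher past the test (7 adjusted over the list alone). Its sum was 1.92-fold higher in replicate 2, through Mir219a-2. With every member that had a count the median was 0.09 (percentile 62.7). The members so added had low counts, at most 16 in a library (Mir124a-2 in replicate 2). As the median and the sum also differed in sign, no direction is given for this list. The remaining lists lay inside the central 95% of random lists. The Dlk1-Dio3 list had a median of 0.04 (percentile 64.4, and a median of 0.09 with 1 value per cluster), with 12 genes higher and 9 lower past the test (21 adjusted over the list alone). The eye, lens and endocrine list had a median of -0.04, and of -0.26 (percentile 5.58) over the 5 members that share no 20-base stretch, with 1 gene higher (Mir375, 0.21) and 2 lower (Mir7b and Mir211) past the test (3 adjusted over the list alone). The muscle list had a median of 0.28, between 0.05 and 0.51 under other minimum counts, with Mir208b higher and Mir206 lower past the test (2 adjusted over the list alone), and its sum was 1.65-fold higher in replicate 2. The erythroid list had a median of -0.16, with Mir451a past the test (1 adjusted over the list alone), and its sum was 2.05-fold higher in replicate 1. The leukocyte and liver lists had medians of -0.05 and -0.05, which turned positive under some alternatives (to 0.05 and 0.11), with 0 genes past the test (0 adjusted over the list alone), and the exact counting intervals of Mir223 and Mir192 included equality. Mir126a, the sole endothelial gene, had a log2 ratio of 0.12 and passed the test (1 adjusted over the list alone). In all, 9 of 15 lists lay outside the central 95%, where 0.75 would by chance if genes moved independently. Without members that share a 20-base stretch 6 of 14 lists lay outside, and with every member that had a count 7 of 15. Genes of 1 genomic cluster need not move independently. With 1 value per cluster, 4 of 13 lists lay outside, the let-7, epithelial, neural and Hox lists, and the Mir183 and Sfmbt2 lists, whose detected members lie within 1 cluster each, had no value.

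**Figure D4:**
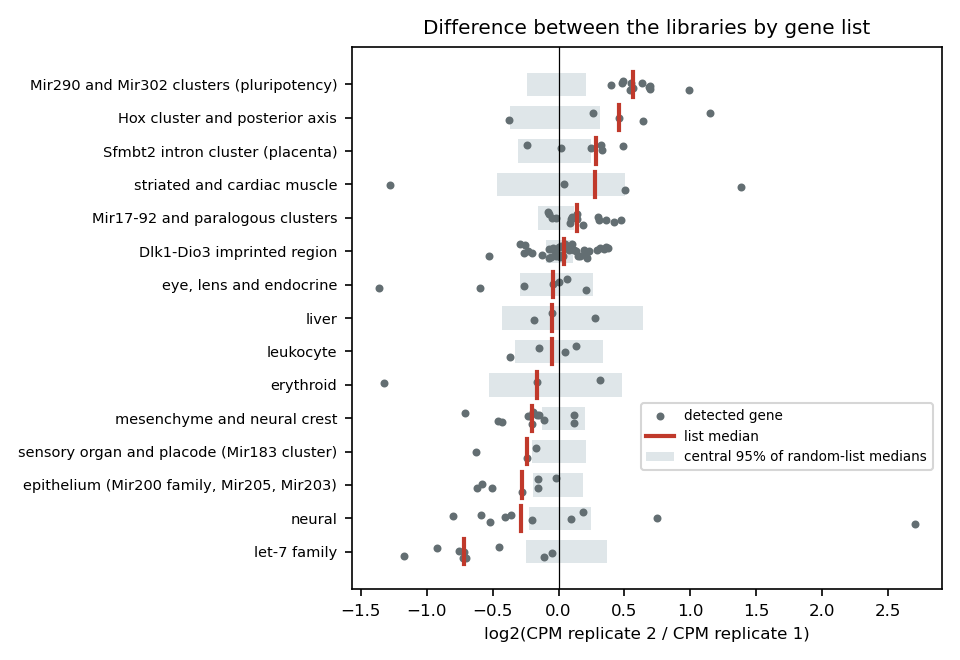
Log2 ratio of CPM, replicate 2 over replicate 1, for each detected gene (points) of 15 gene lists, with the list median (red bar) and the central 95% of medians of 10000 random lists matched on level (grey band). The let-7 median lies at -0.72 and the Mir290 and Mir302 median at 0.56, both outside their bands.

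The widest single genes differed by more than the median of any list. Mir219a-2, of a family that acts in oligodendrocyte differentiation, was 6.53-fold higher in replicate 2 (968 and 7798 counts, chromosome 2, 29845631 to 29845727, ENSMUSG00000065485.1). Mir208b, in an intron of the myosin gene Myh7, was 2.61-fold higher, Mir10a, in the Hoxb region, 2.22-fold, Mir294, of the Mir290 cluster, 1.98-fold, and Mir449a, in an intron of Cdc20b and known from multiciliated cells, 1.78-fold. Lower in replicate 2 were Mir7b with a log2 ratio of -1.37, Mir451a, a miRNA of red blood cells, with -1.32, and Mir206, a skeletal muscle miRNA, with -1.28. Mirlet7i followed with -1.18 and Mir1298, in an intron of Htr2c, with -1.12. These 10 genes were the 5 widest in each direction among genes with a mean of at least 10 CPM that passed the test. Their adjusted p-values by the exact binomial test ran up to 1.5e-05 (Mir206). Mir219a-2 shares a 20-base stretch with 2 other miRNA genes, so reads mapping to more than 1 copy are missing from its count.

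Whether genes with several copies had lower counts depended on the definition, the genes compared and the measure, so no single direction is given. Genes that share a 20-base stretch had the lower median in both sets of genes compared. Among genes with a Mir symbol they were still detected about as often as the others. Among the 1051 genes with a Mir symbol, the 121 whose symbol carries a copy number had a median of 0.175 CPM, against 0.668 CPM for 930 others, held 2.30% of the counts and were detected in 37.2% of cases, against 34.4%. The other 922 genes, with Gm symbols or bare identifiers, were mostly without a count (93.7%). With them included, 1852 genes lacked a copy number, with a median of 0 CPM and 17.9% detected. These 1852 include genes without a Mir symbol that share a 20-base stretch with another, so they are not all single-copy. Taking as multi-copy the genes whose hairpin shares a 20-base stretch with another, the 227 with a Mir symbol had a median of 0.284 CPM against 0.777 CPM for 824 others, held 8.22% of the counts and were detected in 34.8% of cases, against 34.7%. Over all genes, 929 shared such a stretch, with a median of 0 CPM and 9.26% detected, against 0.175 CPM and 27.8% for 1044 others. Reads on the strand of the annotated gene made up 97.6% of gene reads in each library. The reads on the opposite strand, 2.43% in replicate 1 and 2.44% in replicate 2, lay to 99.4% at 10 genes that overlap another annotated miRNA gene, 4 of them in the Dlk1-Dio3 region. They are outside all sums above except the unstranded leukocyte sum, which leaves the Dlk1-Dio3, let-7 and leukocyte sums without those partners.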

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

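The tests in this part were chosen after the result was seen. Only the prediction on the GC content of the hairpins was written before its test was made.

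Reads on the strand opposite to the annotated gene lie outside the counts used for the report. At 22 genes they were above the limit that a count of 0 allows (3 counts) in each library. At 10 of these they came to at least 10 counts and outnumbered the reads on the gene's own strand in each library. Summed over both libraries, Gm24321 had 60785 such counts, Gm25301 22075, Gm25252 16113, Gm24083 16069, Gm25927 13219, Gm25750 12034, Mir299b 9873, Mir142b 4446, Mir497b 3624 and Gm24111 26. In order, M21 annotates on that strand Mir409, Mir378a, Mir376a, Mir191, Mirlet7e, Mir380, Mir299a, Mir142, Mir497 and Mirlet7f-1, and for none of these partners was a gene matched in the tables. Among the other 12 genes, Mir3074-1 had 433, Mir203 127, Mir337 52, Mir708 30, Mir126a 29, Gm25641 19, Mir219a-1 15, Mir183 14, Mir486 13, Mir5618 13, ENSMUSG00000099265 12 and Mir124a-3 8. The first 10 genes held 99.4% of all opposite-strand counts, and their own strand had at most 8 counts in a library. Reads placed on the wrong strand in preparation or counting are argued against, since genes with no annotated miRNA gene opposite them had only 0.00516% of their counts there. A candidate explanation is that the reads belong to the partner gene, since 99.81% of opposite-strand counts lay at genes with an annotated miRNA gene on that strand, so the list sums that lack Mir409, Mir376a, Mir380, Mir299a, Mirlet7e and Mir142 may be too low.

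The let-7 family was lower and the Mir290 and Mir302 clusters were higher in replicate 2, with list medians 1.28 apart on the log2 scale. A linear effect of hairpin GC is argued against as the cause, since the trend was 0.02 log2 per 10% of hairpin GC. The medians stayed 1.29 apart after it was removed. The GC content of the sequenced inserts, which are shorter than the hairpins, was not measured, so an effect of insert GC was not tested. A difference in cell type make-up between the pools stays possible. Of 10 marker lists with a ratio, 5 had medians outside the central 95% of random lists, a count that ignores direction. The epithelial, mesenchymal and Mir183 lists were lower in replicate 2, the Hox list was higher, and no direction is given for the neural list. The 2 main tissue layers thus did not differ in opposite directions. Only 3 of the 5 stayed outside under each alternative that gave a value, and no marker list bears on let-7 or Mir302 directly. The design has 1 group, so there is no biological group to test the difference against, and a small difference in developmental stage between the pools stays open.

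Mir219a-2 was 6.53-fold higher in replicate 2. Counted reads shifted from Mir219a-1 to Mir219a-2 are argued against, since the sum of the 2 genes still had a log2 ratio of 2.09. Reads mapping to both copies are in neither count. The sum therefore cannot decide whether more of the family's reads were counted as unique in replicate 2. Carry-over of neural tissue could not be decided. The other 8 detected neural genes had a median log2 ratio of -0.39, between -0.80 and 0.19, yet the low counts of the neuronal Mir124a genes went with Mir219a-2, 3 in replicate 1 and 29 in replicate 2. The design has no biological group to test this difference against.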

How the results depend on the processing

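The alternatives without members that share a 20-base stretch, without members under a mean of 10 CPM, with 1 value per genomic cluster, or with multi-copy genes compared over all genes, were chosen after the data were examined.

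For the results that answer a comparison, 91 alternative values were scored as unchanged, 9 moved further, 6 lost the call and 1 reversed. Unchanged means that a list median kept its direction and call, that a count stayed within 1.5 times, or that another value stayed within its SD or interval. Thus 104 genomic clusters became 145 with a 50 kb gap, and 376 detected genes became 479 with at least 3 counts and 313 with at least 10 CPM. Of 105 values of other list sums, 87 moved by less than the SD and 18 by more. Leaving out 1 replicate always moves a mean of 2 libraries by less than their SD. Such list sums were therefore scored as unchanged by construction, here and among the 91 values. The 42 medians of uncalled lists all stayed uncalled, but 4 changed sign (leukocyte and liver). Without replicate 1 or replicate 2, 381 to 402 genes were detected, the top 10 genes held 50.07% to 50.18% and the Mir17-92 list summed to 218776 to 224313 CPM. In the unstranded count the top 10 share was 48.9%, the Mir17-92 list 216146 CPM and the share of the Mir17-92 cluster 16.2%, because the opposite-strand reads enlarge the totals. Without Mir335 the top 10 share was 43.4%, since that gene left the sum, and the Mir17-92 list 261858 CPM, since the totals were smaller. Without members that share a 20-base stretch, the Mir17-92 list summed to 210783 CPM and its median ratio was 0.10. The neural median was then -0.053 over 2 genes. Lists outside the central 95% were then 6 of 14. With 1 value per genomic cluster, 4 lists stayed outside the central 95%, and the Mir290 and Mir302 (0.58), mesenchyme (-0.20) and Mir17-92 (0.089) medians kept their sign but lay inside it. Over all genes, 9.26% of those that share a 20-base stretch were detected. With every member that had a count, the neural median was 0.093 over 15 genes, the Sfmbt2 median 0.29 at percentile 94.7, and 7 of 15 lists lay outside. The SD of the ratio was 0.67 with no filter beyond 1 count, and the cause was not tested for the neural, Sfmbt2 and SD values with looser filters. TMM or DESeq2 scaling left 181 genes differing and 9 lists outside the central 95%, and no called list changed direction under either. Either scaling shifts all log2 ratios by nearly the same amount, in a list and in its random lists alike. The percentiles could therefore hardly change, and these values, counted among the 91, are no check of the list calls. The library sizes also changed little, which left the binomial tests little room to change.

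No paired analysis was possible because the design has 1 group. The ratio of a list or gene needs both libraries, so it has no value without either. The endothelial list, the Sfmbt2 list without shared members, and the Mir183 and Sfmbt2 lists by cluster had too few values for a ratio. Depth limits genes under about 10 counts, and reads mapping to several places limit all multi-copy genes at any depth.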

Other observations

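The tests and sums in this part were chosen after the result was seen.

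Loci under genomic imprinting together held 24.9% ± 0.83 of all counts (69 genes, n = 2). This sum leaves out reads on the strand opposite to an annotated gene, some of them in the Dlk1-Dio3 region. The Dlk1-Dio3 region and the Sfmbt2 cluster entered it by the matched members of their lists only. Beside Mir335, the Dlk1-Dio3 region and the Sfmbt2 cluster, Mir296 and Mir298, of the imprinted Gnas region, held 1.28% ± 0.0931. Mir483, in the growth factor gene Igf2, held 0.192% ± 0.0080, and Mir675, made from H19, 0.0169% ± 0.00080. Each of these loci had a ratio between the libraries from 1.04 to 1.23.

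The paralogous clusters of the Mir17-92 list did not have the same ratio between the pools. The cluster of Mir106a, Mir20b and Mir363 on chromosome X (52741693 to 52742567), which held 1.83% ± 0.255, had a median log2 ratio of 0.34 over 6 genes. The Mir17-92 cluster on chromosome 14 had 0.09 over 6 genes, and the cluster in Mcm7 had -0.02 over 3 genes. The difference between the clusters was not tested. The X-linked cluster of Mir322, Mir351 and Mir503 (chromosome X, 53047997 to 53054349) held 2.97% ± 0.0525 of the counts.

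Genes of 1 genomic cluster moved together between the libraries. Over 148 genes in 40 clusters the SD of the log2 ratio within a cluster was 0.24, against 0.33 for random assignments of the genes to clusters (one-sided permutation p = 0.00011, 100000 permutations). A shared primary transcript is a candidate explanation, as a hypothesis. The p was 0.02 over 130 genes without let-7 and the Mir290 and Mir302 clusters, and 0.00083 over 100 genes without members that share a 20-base stretch. A difference in cell type make-up between the pools would also move cluster members together and was not separated from it.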
